A study of Mus musculus with 9 samples.

How the data were processed

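The samples were 9 libraries of a mouse MLL-AF9 leukaemia line with doxycycline-inducible FLT3-ITD. There were 3 libraries each from cells in 1 µg/mL doxycycline (ON) and from cells 24 h (OFF24) and 48 h (OFF48) after it was washed out. Per the labels' protocols, RNA was extracted with TriZol and a column kit with DNase treatment, and libraries were made with the Lexogen QuantSeq 3' kit. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name bcl2fastq 2.17.1.14, FastQC 0.11.2, cutadapt 1.5, HISAT2 2.0.4, Subread 1.5.0-p3 with featureCounts, R 3.6.1, limma 3.42.2 and the build mm10, without saying what each was used for. The gene annotation, the strand setting, the treatment of reads that map to several places and any filters are not given in the sources used here.

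The deposited count table holds whole-number read counts per gene symbol, with a column for each library, not normalised and with replicates not pooled, as its values show. It has 24756 rows, of which 16962 have a count in at least 1 library. Of all symbols, 26 have the form of a date, as spreadsheet software makes of some gene names, and were left under that name. Among rows with a total of at least 200 counts, 191 have the same counts in all 9 libraries as another row, and 220 of the tested rows do. Reads were therefore counted for more than 1 symbol in places. A second deposited table holds log2 expression values that are normalised by voom and limma, per its name in the series. It has 10552 rows with the same maximum in every library, and it served only as an alternative. All columns of both tables were matched to samples by their names.

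Total counts per library ran from 1329296 (OFF48 replicate 2) to 4038456 (ON replicate 2). A floor of 3 counts, the limit that a count of 0 allows, corresponds to 0.74 CPM in the deepest library and 2.26 CPM in the shallowest. Reads were amplified by PCR without molecular identifiers in these tables, so floors cover counting error only. Replicates of a group differed by more than counting noise (chi-square per degree of freedom 1.99 to 6.99 over genes with at least 20 counts in a pair), with correlations of log2 CPM of 0.962 to 0.986 across genes, which are not independent replicates. None were identical, and each library was counted once. The common biological coefficient of variation was 0.105.

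Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, leaving 10215, libraries were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group was fitted to all 9 libraries. The groups thus share an estimate of the spread with 6 residual degrees of freedom. The comparisons were OFF24 with ON, OFF48 with ON and OFF48 with OFF24, which also tests whether the changes at the 2 times differ. P-values were adjusted by Benjamini-Hochberg (BH) over all tested genes with a threshold of 0.05, and genes that changed at least 2-fold were counted in addition. Group levels are means of TMM-scaled CPM with the SD.

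The gene lists were fixed before the data were examined. They covered serine synthesis, one-carbon and folate enzymes, ATF4 targets, cytosolic aminoacyl-tRNA synthetases, amino acid transporters, STAT5 targets, ERK pathway output, MYC and ribosome biogenesis, glycolysis, cholesterol and fatty acid synthesis, purine and pyrimidine synthesis, S phase, G2 and M phase, azurophil granule and early myeloid genes, neutrophil maturation, monocytes and macrophages, the MLL-AF9 program, the BCL2 family, FOXO targets, the interferon response, MHC class II, ER chaperones, p53 targets, heat shock, lysosome, mitochondrially encoded genes, nuclear OXPHOS subunits, mitochondrial proteostasis and ribosomal proteins. A further 4 lists held markers of other cell types. Some genes stand in more than 1 list. Mitochondrial genes bear short symbols in the count table (ND1, COX1), and their match to the listed names was set after the table was seen. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01, BH over the lists of a comparison, with an estimated correlation and fry beside it. Fry asks whether a list moves on balance and does not compare it with other genes.

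Named genes were chosen by a rule fixed before the data were examined. It takes, against ON, the 6 rises and 6 falls of largest log2 fold change (4 and 4 between OFF24 and OFF48) among genes past the threshold with a mean of at least 10 CPM and no overlap between the libraries of the groups, leaving out unnamed gene models. It adds Phgdh, Psat1, Psph, Atf4, Flt3, Myc and Pim1 whatever their result, and up to 4 tested members of each list with the smallest p. Positions come from GENCODE M21 on GRCm38, the build also called mm10, and gene ends there can differ from those of the annotation used for counting. The last 400 bases of each listed or named protein-coding gene, and of gene families looked at after the results were seen, were compared with all GENCODE M21 transcripts by blastn 2.17.0, and a match of at least 50 bases at 95% identity was taken as a shared 3' end, found for 187 of 768 genes.

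The fits were tested on simulated counts of 9855 genes drawn from the means of the ON libraries, the fitted dispersions and the depths of all 9, with genes changed by known folds. For OFF24 against ON the test recovered 36.9% of genes changed 1.5-fold, 87.3% at 2-fold and 96.9% at 4-fold, with 11 false calls among 158. For OFF48 against ON it recovered 40.6%, 89.6% and 98.5%, with 10 false calls among 165. For OFF48 against OFF24 it recovered 46.5%, 89.2% and 97.7%, with 16 false among 318. No changed gene was called in the wrong direction. A planted list of 20 genes changed 1.5-fold was called in both comparisons with ON (camera adjusted p = 3.34e-14 and 2.99e-13) and not between the OFF groups, where it did not differ (camera adjusted p = 0.976). Of 29 other lists, 0, 1 and 0 were called. The simulated genes varied independently, while members of real lists can vary together (estimated correlation 0.396 for mitochondrially encoded genes, OFF48 against ON). These counts therefore do not show how often camera errs on such lists. Far fewer genes changed than in the real comparisons, so the recovery rates may not carry over.

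The alternatives fixed in advance were RLE, upper quartile and library-size scaling, DESeq2 1.42.0, limma-voom, limma on the deposited normalised values, no filter on low counts, a filter of 5 CPM in 3 libraries, a fit to the 2 groups compared alone, the replicate number as a block, and leaving out each library. Chosen after seeing the data were collapsing rows with the same counts to 1 row and leaving out S100a8 and S100a9. The overlap of calls at both times was set beside 20 simulations of unchanged groups against the shared ON libraries. The result of 1 further member of a list is not reported here. Sequencing reads were not analysed here, and no sample was left out of the main comparisons.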

Results

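Gene expression was measured by 3' mRNA sequencing, which reads the 3' ends of polyadenylated transcripts, in a mouse acute myeloid leukaemia cell line. The line was derived from fetal liver cells and carries 2 retroviral vectors. MLL-AF9, a fusion protein that drives leukaemia, is made constitutively, and FLT3-ITD, a receptor tyrosine kinase that signals without its ligand, is made only while doxycycline is in the medium. The 9 libraries fall into 3 groups of 3: cells kept in 1 µg/mL doxycycline (ON), and cells 24 h (OFF24) and 48 h (OFF48) after the drug was washed out. Library totals ran from 1329296 counts in OFF48 replicate 2 to 4038456 in ON replicate 2, and 10215 genes were tested. Levels are normalised read counts scaled to library size (CPM) with the SD over n = 3 libraries. Log2 fold changes carry an approximate standard error (SE), their size divided by the square root of the quasi-likelihood F statistic. For genes with few counts in a group, such as Etv4, Etv5 and Phgdh at 48 h, it can be smaller than counting error alone. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

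The mouse Flt3 gene (chromosome 5, 147330741 to 147400489 in mm10) had 2 to 10 counts in each library and was not tested. A transcript of the vector ends in vector sequence, outside the mouse gene, so 3' counts of Flt3 check neither the transgene nor its loss. Markers of other cell types of the fetal liver were low in all groups. Lymphoid markers summed to 7.5 CPM in ON, 12.7 in OFF24 and 10.2 in OFF48. Megakaryocyte, mast cell and basophil markers summed to 18.8, 28.1 and 16.4 CPM, and the tested ones moved apart, Mcpt8 rising at 24 h (log2 1.55 ± 0.25, SE, edgeR adjusted p = 8.41e-05) and Gata2 falling at 48 h (log2 -1.76 ± 0.40, edgeR adjusted p = 0.00116). Hepatocyte and stromal markers summed to 37.6, 59.5 and 65.1 CPM, most of it from Pecam1, an adhesion molecule that myeloid cells also carry. Erythroid markers summed to 89.8, 89.8 and 117.7 CPM, nearly all from Tfrc, the transferrin receptor of dividing cells.

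The comparison of OFF24 with ON asked what changed within 24 h of washing out doxycycline, in a series whose title names serine synthesis. All 3 genes of the serine synthesis pathway fell. Phgdh, whose enzyme commits a glycolytic intermediate to serine, went from 107 ± 10.6 CPM (SD, n = 3) in ON to 22.5 ± 2.73 in OFF24, a log2 fold change of -2.24 ± 0.14 (SE). Psat1, the aminotransferase of the pathway, went from 251 ± 11.1 to 90.8 ± 2.38 CPM (log2 -1.47 ± 0.10) and Psph, the phosphatase that releases serine, from 58.3 ± 4.15 to 26.0 ± 5.46 CPM (log2 -1.18 ± 0.16). Atf4, the transcription factor of the amino acid and integrated stress responses, went from 896 ± 88.7 to 331 ± 11.2 CPM (log2 -1.44 ± 0.14).

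The edgeR quasi-likelihood adjusted p-values were 1.09e-09 for Phgdh, 4.91e-09 for Psat1, 1.83e-05 for Psph and 7.75e-07 for Atf4. All 3 serine synthesis genes also fell when adjusted over the list alone, and the list fell as a set (camera adjusted p = 7.6e-10). Camera calls given without a value for an estimated correlation also held with one, but with much larger adjusted p-values. For the MYC and ribosome biogenesis list at 24 h, the camera adjusted p was 1.33e-32 at the preset correlation and 0.00133 with an estimated one. In mm10 (GRCm38, GENCODE M21), Phgdh lies on chromosome 3 from 98313170 to 98339990, Psat1 on chromosome 19 from 15904678 to 15947337 and Psph on chromosome 5 from 129765558 to 129787449, all on the minus strand, and Atf4 on chromosome 15 from 80255184 to 80257541 on the plus strand. The 3' end of Phgdh is shared, at 95% identity or more, with 12 other annotated genes, so its level is uncertain to the extent that reads could be split among them. Psat1, Psph and Atf4 have no such match.

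**Figure D1:**
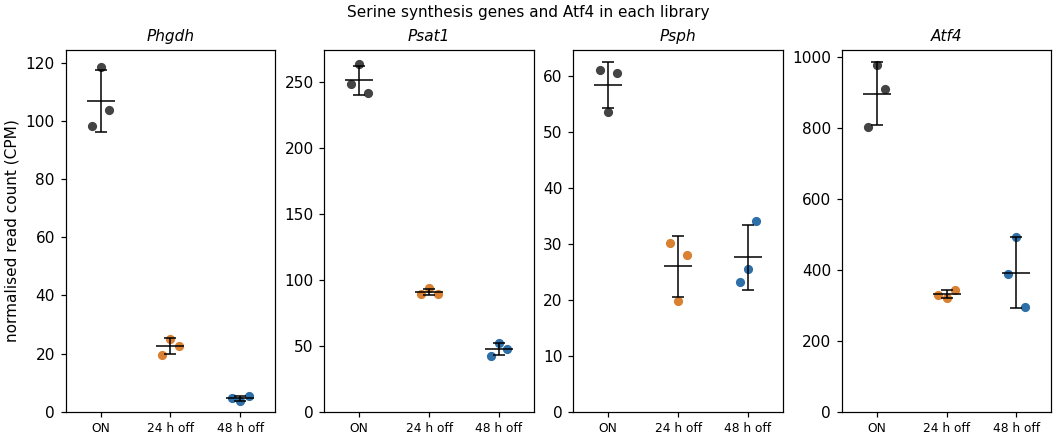
Normalised read count (CPM, linear axis from 0) of Phgdh, Psat1, Psph and Atf4 in each library, by group; points are libraries, bars are the mean and SD of 3 libraries. Every OFF24 and OFF48 library lies below every ON library for all 4 genes, and Phgdh averages 107 CPM in ON, 22.5 in OFF24 and 4.66 in OFF48.

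Genes that supply and use amino acids fell with them at 24 h. Of 24 tested targets of ATF4, 21 fell and 0 rose, with the same counts when adjusted over the list alone (median log2 -1.23, camera adjusted p = 2.96e-18). Trib3, a pseudokinase induced by ATF4, fell by 2.97 ± 0.23 (SE) on the log2 scale, and Cth, which makes cysteine, fell by 2.96 ± 0.15. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 17 fell and 0 rose, again the same when adjusted over the list alone (median log2 -1.03, camera adjusted p = 8.52e-17). Among these Farsb stood at log2 -1.45 ± 0.11 and Gars at -1.40 ± 0.11. The one-carbon and folate enzymes, which take up carbon units from serine, had 8 of 15 genes down and 2 up (10 and 2 when adjusted over the list alone, median log2 -1.02, camera adjusted p = 3.69e-07). Mthfd2, the mitochondrial folate enzyme, fell by 2.07 ± 0.11 and Shmt2, which splits serine into glycine and a carbon unit, by 1.23 ± 0.12, and both are also members of the ATF4 list. Of 15 amino acid transporters 7 fell and 3 rose (8 and 3 when adjusted over the list alone, camera adjusted p = 0.000118). Slc7a5, a leucine carrier, fell by 2.66 ± 0.15, while the lysosomal carrier Slc36a1 rose (log2 0.92 ± 0.11). Purine and pyrimidine synthesis genes had 13 of 19 down and 1 up, as they did when adjusted over the list alone (median log2 -0.98, camera adjusted p = 5.3e-08), with Cad, the entry enzyme of pyrimidine synthesis, at log2 -1.68 ± 0.19.

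The transcriptional output of signalling downstream of growth factor receptors also fell at 24 h. Of 15 STAT5 targets 11 fell and 0 rose (11 when adjusted over the list alone, median log2 -1.13, camera adjusted p = 3.96e-08). Pim1, a survival kinase, went from 405 ± 51.0 CPM (SD, n = 3) to 175 ± 9.59 (log2 -1.21 ± 0.11, SE), and Ccnd2, a G1 cyclin, fell by 2.01 ± 0.21 on the log2 scale. Of 13 genes that report ERK activity 8 fell and 0 rose (8 when adjusted over the list alone, median log2 -1.52, camera adjusted p = 2.03e-07). Among them, the ETS factors Etv4 and Etv5 went from 22.9 ± 2.25 to 0.821 ± 0.787 CPM and from 31.0 ± 4.24 to 3.10 ± 0.691 CPM. In the list of MYC and ribosome biogenesis genes 28 of 30 fell and 0 rose (28 when adjusted over the list alone, median log2 -1.39, camera adjusted p = 1.33e-32). Myc itself fell by 1.41 ± 0.22, and Srm, which makes spermidine, fell by 2.46 ± 0.17.

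Cholesterol and fatty acid synthesis had 22 of 31 genes down and 0 up (23 when adjusted over the list alone, median log2 -0.66, camera adjusted p = 2.94e-11), with Lss at log2 -1.40 ± 0.18 (SE) and Fasn, the fatty acid synthase, at -0.91 ± 0.11. Mitochondrial chaperones and proteases had 13 of 16 down and 0 up (14 when adjusted over the list alone, camera adjusted p = 2.1e-07). Heat shock genes had 8 of 14 down and 0 up (10 when adjusted over the list alone, camera adjusted p = 1.8e-06). Hspd1, the mitochondrial chaperonin that stands in both lists, fell by 1.45 ± 0.12 on the log2 scale, and its 3' end is shared with other annotated genes. Glycolysis genes moved the other way. Of 23, 12 rose and 3 fell (13 and 3 when adjusted over the list alone, median log2 0.33, camera adjusted p = 0.00838), and the list was not called with an estimated correlation (adjusted p = 0.209 with an estimated correlation) or without ON replicate 3 (camera adjusted p = 0.0512). Pgk1 went from 980 ± 85.9 to 1606 ± 65.6 CPM and Pdk1, a pyruvate dehydrogenase kinase, from 74.0 ± 11.4 to 131 ± 11.6 CPM, while the lactate carrier Slc16a1 fell by 1.56 ± 0.19.

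Genes of myeloid differentiation rose at 24 h. Of 13 azurophil granule and early myeloid genes 9 rose and 0 fell (10 and 1 when adjusted over the list alone, median log2 0.92, camera adjusted p = 3.96e-08). Mpo, the granule peroxidase, went from 69.1 ± 12.1 to 341 ± 46.5 CPM (SD, n = 3). Of 11 tested monocyte and macrophage genes 10 rose and 0 fell (10 when adjusted over the list alone, median log2 0.98, camera adjusted p = 5.05e-07), with Csf1r, the receptor for macrophage colony-stimulating factor, at log2 1.98 ± 0.21 (SE). Of 22 neutrophil maturation genes 10 rose and 1 fell (11 and 2 when adjusted over the list alone, median log2 0.45, camera adjusted p = 0.000112), a call not kept with an estimated correlation (adjusted p = 0.0587 with an estimated correlation). Camp, a granule antimicrobial peptide, rose by 1.70 ± 0.11. The MLL-AF9 stem and progenitor genes had 13 of 17 up and 1 down (the same when adjusted over the list alone, median log2 0.55, camera adjusted p = 3.69e-05), among them Hoxa5 (log2 1.21 ± 0.12) and Myb (0.79 ± 0.10). FOXO targets had 14 of 22 up and 1 down (15 and 1 when adjusted over the list alone, median log2 0.66, camera adjusted p = 1.65e-06). Ypel3 (log2 1.63 ± 0.12) and Txnip (1.42 ± 0.09) rose, and Klf2 fell by 1.68 ± 0.13. Lysosomal genes had 12 of 29 up and 1 down (13 and 1 when adjusted over the list alone, camera adjusted p = 0.00343, and adjusted p = 0.0792 with an estimated correlation).

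S phase genes had 7 of 30 down and 0 up (7 when adjusted over the list alone, median log2 -0.22, camera adjusted p = 0.0123, and adjusted p = 0.0539 with an estimated correlation), with Mcm2, a subunit of the replicative helicase, at log2 -0.59 ± 0.11 (SE). The remaining lists were not called as sets by camera at 24 h. G2 and M phase genes had 6 of 30 down (adjusted p = 0.178), BCL2 family genes 7 of 15 down and 1 up (adjusted p = 0.0703), and p53 targets 6 of 16 down and 3 up (adjusted p = 0.152). Adjusted over the list alone, those counts were 6 down, 8 down with 2 up, and 8 down with 3 up. The BCL2 list passed without ON replicate 2 (adjusted p = 0.0218), and with no filter on low counts it passed (0.00944), as did G2 and M phase genes (0.0106) and p53 targets (0.0361). ER chaperones had 9 of 20 down and 0 up (10 and 3 when adjusted over the list alone, adjusted p = 0.0502), and passed without any of 6 libraries in turn, for example without OFF24 replicate 3 (adjusted p = 0.0291). They also passed with RLE (adjusted p = 0.0478) or library-size scaling (0.0461), DESeq2 (0.0139), limma-voom (0.0419), no filter on low counts (0.00333) and a fit to the groups compared alone (0.0413), so the list lay at the threshold. Interferon response genes had 3 of 15 down and 1 up (1 and 0 when adjusted over the list alone, adjusted p = 0.502), and MHC class II genes 2 of 5 up (2 when adjusted over the list alone, adjusted p = 0.187). Ribosomal proteins had 1 of 45 up and 1 down (1 and 0 when adjusted over the list alone, adjusted p = 0.481). Mitochondrially encoded genes had 2 of 13 up and 3 down (the same when adjusted over the list alone, adjusted p = 0.328). Nuclear OXPHOS subunits had 2 of 42 up and 5 down (1 and 3 when adjusted over the list alone, adjusted p = 0.548), with a median of 0.02 and a mean of -0.02 on the log2 scale.

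Across all tested genes, 1822 rose and 1781 fell between ON and OFF24 (3603 together, edgeR quasi-likelihood, BH), of which 449 and 442 changed at least 2-fold. Under upper quartile scaling 2070 rose and 1600 fell, or 56.4% up against 50.6%. The largest rises under the rule for named genes were those of Lyz2 (log2 2.75 ± 0.16, SE), F13a1 (2.54 ± 0.24), Lyz1 (2.54 ± 0.15), Fcnb (2.44 ± 0.23), the small nuclear RNA Rn7sk (2.42 ± 0.17) and Osbpl3 (2.36 ± 0.15). Rn7sk is not a protein-coding gene, and whether its reads come from polyadenylated transcripts was not tested, so its level is uncertain. Lyz1 and Lyz2, the lysozyme genes, share their 3' ends and were counted as an uncertain pair, and the 3' end of Lilr4b is shared with Lilrb4a. The largest falls were those of Etv4 (log2 -4.63 ± 0.38), Car4 (-3.95 ± 0.14), Etv5 (-3.34 ± 0.24), Trib3, Cth and Lilr4b (-2.79 ± 0.24). Car4, a carbonic anhydrase of the cell surface on chromosome 11 from 84957786 to 84966044, went from 1028 ± 89.2 CPM (SD, n = 3) in ON to 66.8 ± 4.72 in OFF24.

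The comparison of OFF48 with ON asked what the expression state was after 48 h without doxycycline. Phgdh stood at 4.66 ± 0.896 CPM (SD, n = 3) against 107 ± 10.6 in ON, a log2 fold change of -4.44 ± 0.18 (SE), and Psat1 at 47.3 ± 4.57 against 251 ± 11.1 (log2 -2.43 ± 0.11). Psph stood at 27.6 ± 5.77 CPM (log2 -1.05 ± 0.17) and Atf4 at 392 ± 99.9 CPM (log2 -1.20 ± 0.14). The edgeR quasi-likelihood adjusted p-values of these genes were 8.87e-13, 3.65e-12, 3.65e-05 and 2.12e-06. The 3 serine synthesis genes fell also when adjusted over the list alone (median log2 -2.43, camera adjusted p = 6.04e-10).

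Lists for amino acid use were also low at 48 h. ATF4 targets had 18 of 24 down and 0 up (18 when adjusted over the list alone, median log2 -1.11, camera adjusted p = 8.18e-11), with Stc2 at log2 -3.75 ± 0.26 (SE), Cth at -3.52 ± 0.16 and Trib3 at -3.00 ± 0.24. All 20 aminoacyl-tRNA synthetases fell, as they did when adjusted over the list alone (median log2 -1.07, camera adjusted p = 4.55e-11). One-carbon enzymes had 10 of 15 down and 2 up (10 and 2 when adjusted over the list alone, camera adjusted p = 0.00015), with Mthfd2 at log2 -1.44 ± 0.10 and Gcsh, of the glycine cleavage system, at -1.79 ± 0.19. Purine and pyrimidine genes had 14 of 19 down and 0 up (15 when adjusted over the list alone, median log2 -0.88, camera adjusted p = 3.52e-06), with Atic, whose 3' end is shared with other annotated genes, at log2 -1.38 ± 0.12. Amino acid transporters had 6 of 15 down and 3 up (6 and 4 when adjusted over the list alone) and were not called as a set (camera adjusted p = 0.0622, and 0.0414 without ON replicate 3). Slc7a5 stood at log2 -3.25 ± 0.17 and Slc36a1 at 1.52 ± 0.11.

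STAT5 targets had 11 of 15 down and 0 up at 48 h (11 when adjusted over the list alone, median log2 -2.13, camera adjusted p = 3.47e-11). Pim1 stood at 50.1 ± 6.54 CPM (SD, n = 3; log2 -3.02 ± 0.13, SE) and Cish, a feedback inhibitor of STAT5 signalling, at log2 -3.21 ± 0.18. ERK output genes had 9 of 13 down and 1 up (9 and 1 when adjusted over the list alone, median log2 -1.35 with Etv4 either as fitted or at its bound, camera adjusted p = 1.2e-05). Etv4 had 0 counts in the OFF48 libraries, which makes it at least 59.1-fold lower than in ON by a floor of 3 counts over the group, and Etv5 stood at log2 -5.50 ± 0.34. The MYC and ribosome biogenesis list had 28 of 30 down and 0 up (28 when adjusted over the list alone, median log2 -1.57, camera adjusted p = 1.2e-24), with Myc at log2 -1.79 ± 0.24 and Srm at -2.90 ± 0.19. Ribosomal proteins had 30 of 45 down and 0 up (30 when adjusted over the list alone, median log2 -0.33, camera adjusted p = 2.35e-05), although many of them, such as Rps2 (log2 -1.34 ± 0.09) and Rpl3 (-0.85 ± 0.09), share 3' ends with pseudogenes.

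Glycolysis genes were lower than ON at 48 h. Of 23, 17 fell and 5 rose (the same when adjusted over the list alone, median log2 -1.48, camera adjusted p = 1.64e-09). Aldoc stood at 40.7 ± 7.52 CPM against 204 ± 34.8 in ON (SD, n = 3), Pgk1 at 324 ± 57.4 against 980 ± 85.9, and Ldha, the lactate dehydrogenase subunit, at 299 ± 26.9 against 1221 ± 121. The 3' ends of Ldha and Eno1 match pseudogenes, and those of Pgk1 and Aldoc match no other gene. Cholesterol and fatty acid synthesis had 27 of 31 down and 0 up (27 when adjusted over the list alone, median log2 -1.11, camera adjusted p = 3.23e-16), with the desaturase Scd2 at log2 -3.12 ± 0.12 (SE) and Acat2, whose 3' end is shared with Acat3, at -1.31 ± 0.12. Heat shock genes had 10 of 14 down (10 when adjusted over the list alone, camera adjusted p = 7.59e-08), with Hsp90ab1, which shares its 3' end with Gm6368, at log2 -1.68 ± 0.10, and mitochondrial proteostasis genes 14 of 16 (15 when adjusted over the list alone, camera adjusted p = 2.2e-09), with Lonp1 at log2 -1.38 ± 0.12. Mitochondrially encoded genes had 10 of 13 down (10 when adjusted over the list alone, median log2 -0.82, camera adjusted p = 8.02e-06, and adjusted p = 0.12 with an estimated correlation), and they took 1.68% ± 0.12 of counts in OFF48 against 2.16% ± 0.14 in ON. Nuclear OXPHOS subunits had 16 of 42 down and 1 up (15 and 1 when adjusted over the list alone, camera adjusted p = 0.0205), a call lost with an estimated correlation (adjusted p = 0.336 with an estimated correlation) and without OFF48 replicate 2 (camera adjusted p = 0.0678).

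Granule and maturation genes of neutrophils were high at 48 h. Of 22 neutrophil maturation genes 18 rose and 0 fell (18 when adjusted over the list alone, median log2 1.85, camera adjusted p = 4.87e-27). Camp stood at 5167 ± 430 CPM (SD, n = 3) against 202 ± 26.1 in ON, and Chil3, a chitinase-like protein of granulocytes whose 3' end is shared with Chil4, at 1275 ± 213 against 110 ± 20.9. S100a8 and S100a9, the calprotectin genes, together took 4.51% ± 0.31 of all counts in OFF48 and 1.31% ± 0.13 in ON. Retnlg and Cxcr2, genes of late neutrophils on the same list, had at most 6 and 12 counts in any library and were not tested. Azurophil granule genes had 9 of 13 up and 2 down (9 and 2 when adjusted over the list alone, median log2 1.08, camera adjusted p = 4.79e-07), with Mpo at 759 ± 97.4 CPM. Monocyte and macrophage genes had 9 of 11 up and 1 down (9 and 1 when adjusted over the list alone, camera adjusted p = 3.93e-05, and adjusted p = 0.0788 with an estimated correlation), with Ly6c2 at log2 1.44 ± 0.10 (SE). The 3' end of Ly6c2 is shared with Ly6c1. MLL-AF9 program genes had 10 of 17 up and 2 down (11 and 2 when adjusted over the list alone, camera adjusted p = 0.00241), with Hoxa5 at log2 1.28 ± 0.12, Myb at 1.21 ± 0.10 and Bcl2 at -2.86 ± 0.36. Lysosomal genes had 15 of 29 up and 4 down (16 and 4 when adjusted over the list alone, camera adjusted p = 0.000339).

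At 48 h FOXO targets had 12 of 22 up and 1 down (12 and 1 when adjusted over the list alone, camera adjusted p = 0.00414, and adjusted p = 0.119 with an estimated correlation). G2 and M phase genes had 12 of 30 down and 1 up (12 and 1 when adjusted over the list alone, camera adjusted p = 0.0185, and adjusted p = 0.346 with an estimated correlation), with the mitotic cyclin Ccnb1, whose 3' end matches pseudogenes, at log2 -0.92 ± 0.11 (SE). That call was also lost without OFF48 replicate 3 (camera adjusted p = 0.0516). ER chaperones had 10 of 20 down and 3 up (10 and 3 when adjusted over the list alone, camera adjusted p = 0.0457, and adjusted p = 0.103 with an estimated correlation), and this call was lost without ON replicate 1 (camera adjusted p = 0.0565) and without OFF48 replicate 1 (0.0652), with the stricter filter (0.0538) and in a fit to the groups compared alone (0.0577). Not called as sets were S phase genes (5 of 30 up, 2 down, adjusted p = 0.601, median -0.01 and mean 0.06 on the log2 scale), BCL2 family genes (9 of 15 down, 2 up, adjusted p = 0.147), p53 targets (9 of 16 down, 2 up, adjusted p = 0.0622), interferon response genes (4 of 15 down, 1 up, adjusted p = 0.378) and MHC class II genes (2 of 5 up, 2 down, adjusted p = 0.942). Adjusted over the list alone, S phase genes had 2 up and 1 down and the others had unaltered counts. The p53 list would be called without any of 7 of the 9 libraries in turn, for example without OFF48 replicate 3 (camera adjusted p = 0.0205), with DESeq2 (0.0379) and with no filter on low counts (0.00733), where the BCL2 list would be called too (0.0237). Its member Cdkn1a, a cyclin-dependent kinase inhibitor that is also a STAT5 target, stood at log2 -2.13 ± 0.17.

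In all, 2395 genes rose and 2446 fell between ON and OFF48 (4841 together, edgeR quasi-likelihood, BH), 801 and 901 of them at least 2-fold. The largest rises were those of Rgs5, a regulator of G protein signalling (log2 5.29 ± 0.23, SE), Camp (4.68 ± 0.12), Lyz2 (4.44 ± 0.17), Lyz1 (4.33 ± 0.15), Fcnb (4.30 ± 0.20) and Ltf, the lactoferrin gene (4.30 ± 0.41). The largest falls were those of Etv4, whose place among them is not known from 0 counts, Car4 (log2 -7.61 ± 0.19), Etv5, Ak4 (-5.09 ± 0.32), Gvin1 (-4.72 ± 0.24) and S100a6 (-4.71 ± 0.14). Ak4 and Gvin1 share their 3' ends with another annotated gene each. OFF48 replicate 2 had the lowest total and lay apart from the other OFF48 libraries on the second principal component, and without it 4835 genes were called, 1850 at least 2-fold.

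**Figure D2:**
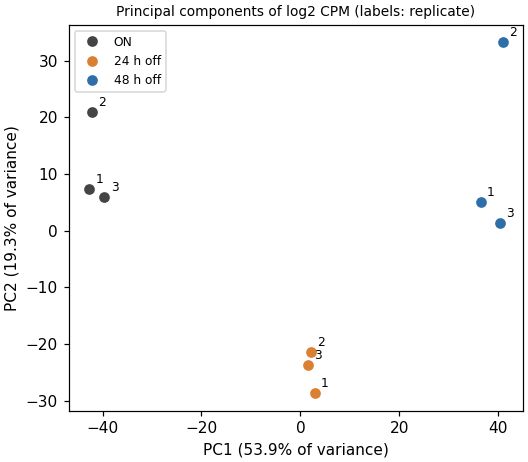
Principal components of log2 CPM over the tested genes; points are libraries, labelled by replicate and coloured by group. PC1 (53.9% of variance) orders the groups ON, OFF24 and OFF48, and OFF48 replicate 2 lies at 33.25 on PC2 against 5.11 and 1.29 for the other OFF48 libraries.

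Both times were compared with the same ON libraries. The calls shared a direction for 2720 genes, of which 1313 rose and 1407 fell at both times. Independent lists of the same sizes would share 427.2 rises and 426.5 falls. In 20 simulations of unchanged groups against these ON libraries, a mean of 0.1 calls were shared. No gene changed in these simulations, so almost no calls were to be expected. The mean of 0.1 therefore does not measure what shared controls add among real changes. At an unadjusted p under 0.05, 3357 genes passed at both times in the same direction against a simulated mean of 89.6. The fold changes had the same sign in 78.1% of genes, against 65.4% in the simulations. Part of the excess over independent lists may come from the shared controls, since 3 ON libraries cannot be split into parts of 2 or more each.

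**Figure D3:**
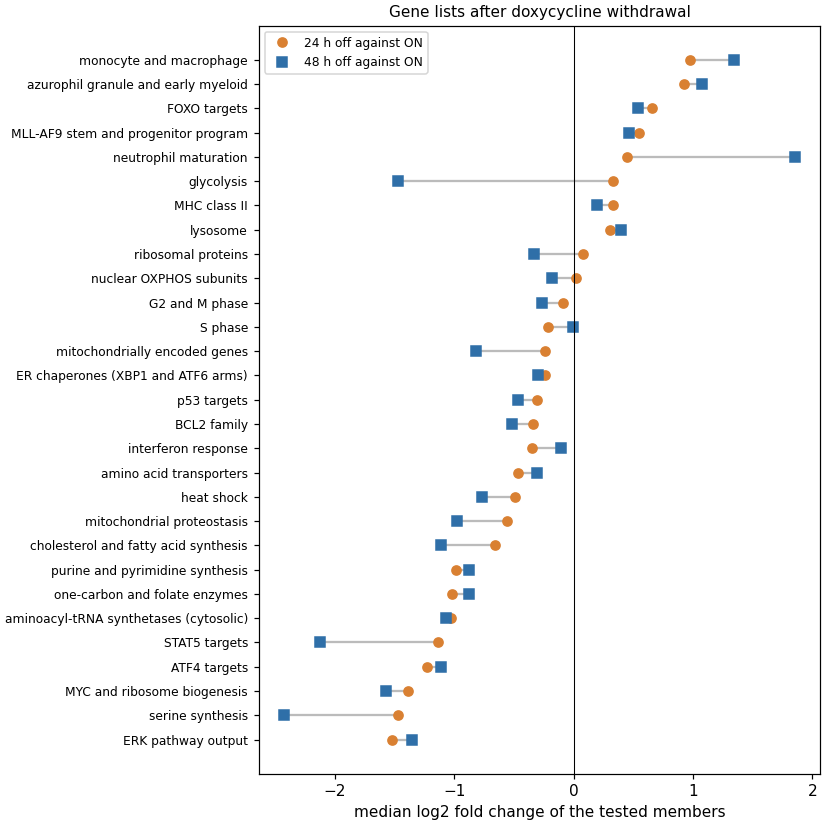
Median log2 fold change of the tested members of each gene list, at 24 h (circles) and 48 h (squares) against ON, with a grey line joining the times. The glycolysis list lies at 0.33 at 24 h and -1.48 at 48 h, and the serine synthesis list at -1.47 and -2.43.

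The comparison of OFF48 with OFF24 asked which changes went on, stopped or turned between the times. Phgdh fell further, by 2.20 ± 0.22 (SE) on the log2 scale, and Psat1 by 0.96 ± 0.12 (edgeR adjusted p = 5.57e-07 and 6.21e-06), while Psph (log2 0.12 ± 0.18), Atf4 (0.23 ± 0.14) and Myc (-0.38 ± 0.29) did not pass the test. Without OFF48 replicate 3, Atf4 stood at log2 0.43 and passed (edgeR adjusted p = 0.0175). Of the 3 serine synthesis genes 2 fell, also when adjusted over the list alone (median log2 -0.96, camera adjusted p = 0.00315), a call lost with an estimated correlation (adjusted p = 0.0573 with an estimated correlation). STAT5 targets had 8 of 15 down and 1 up (10 and 1 when adjusted over the list alone, median log2 -0.99, camera adjusted p = 7.19e-06), with Pim1 at log2 -1.81 ± 0.13, Cish at -1.96 ± 0.20 and Bcl2l1 at 1.13 ± 0.17.

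Glycolysis genes fell and neutrophil maturation genes rose between 24 h and 48 h. Of 23 glycolysis genes 17 fell and 1 rose (18 and 1 when adjusted over the list alone, median log2 -1.29, camera adjusted p = 2.56e-36). With an estimated correlation the camera adjusted p of this list was 0.0053. Aldoc went from 318 ± 22.9 to 40.7 ± 7.52 CPM (SD, n = 3), Pgk1 from 1606 ± 65.6 to 324 ± 57.4 and Pdk1 from 131 ± 11.6 to 18.3 ± 2.39. Of 22 neutrophil maturation genes 20 rose and 1 fell (20 and 2 when adjusted over the list alone, median log2 1.36, camera adjusted p = 4.89e-39). For these genes an estimated correlation gave a camera adjusted p of 0.00341. Camp went from 658 ± 45.6 to 5167 ± 430 CPM and Chil3 from 149 ± 6.48 to 1275 ± 213. Ltf had 3 counts over the OFF24 libraries (0.303 ± 0.298 CPM) and stood at 21.1 ± 6.45 CPM in OFF48.

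**Figure D4:**
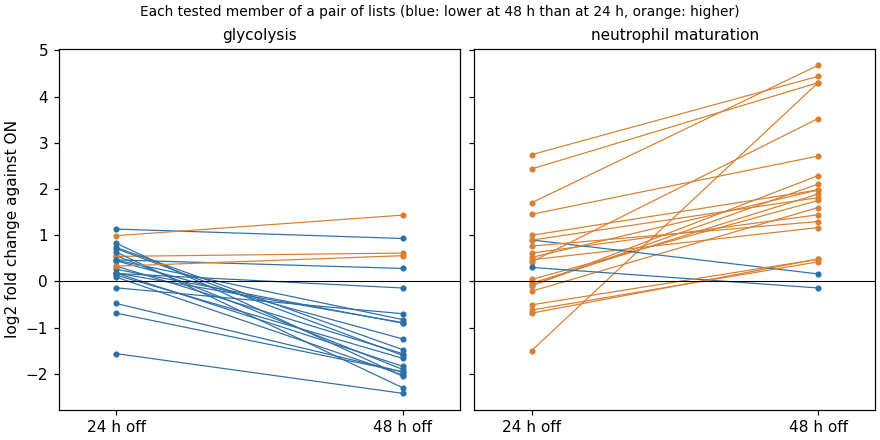
Log2 fold change against ON of each tested member of the glycolysis (23 genes) and neutrophil maturation (22 genes) lists at 24 h and 48 h; each line is a gene, blue where the value is lower at 48 h than at 24 h and orange where it is higher. Of the glycolysis genes 20 lines go down, and of the neutrophil genes 20 go up.

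S phase genes had 9 of 30 up and 0 down between 24 h and 48 h (9 when adjusted over the list alone, median log2 0.29, camera adjusted p = 0.000372), with Mcm2 at log2 0.76 ± 0.11 (SE). Ribosomal proteins had 33 of 45 down and 0 up (38 when adjusted over the list alone, median log2 -0.42, camera adjusted p = 8.52e-14). Cholesterol and fatty acid synthesis had 17 of 31 down (18 when adjusted over the list alone, median log2 -0.41, camera adjusted p = 2.29e-07), with Scd2 at log2 -2.47 ± 0.12 and Fdps, whose 3' end is shared with other annotated genes, at -0.97 ± 0.15. Mitochondrial proteostasis genes had 6 of 16 down (6 when adjusted over the list alone, camera adjusted p = 0.00141), with Lonp1 at log2 -0.92 ± 0.13. Mitochondrially encoded genes had 7 of 13 down (8 when adjusted over the list alone, camera adjusted p = 3.64e-08, and adjusted p = 0.131 with an estimated correlation). ND6, the only one of them on the minus strand, went from 118 ± 8.47 to 3.40 ± 1.67 CPM, and its reads cannot be told from those of the opposite strand, as no strand setting is stated. Heat shock genes had 5 of 14 down (6, with 1 up, when adjusted over the list alone, camera adjusted p = 0.00529, and adjusted p = 0.234 with an estimated correlation), with Hsp90ab1 at log2 -1.45 ± 0.10. Nuclear OXPHOS subunits had 8 of 42 down (7 when adjusted over the list alone, camera adjusted p = 0.00561, and adjusted p = 0.335 with an estimated correlation). MYC and ribosome biogenesis genes had 4 of 30 down (3 when adjusted over the list alone, camera adjusted p = 0.021, and adjusted p = 0.271 with an estimated correlation), with Npm1, whose 3' end is also shared with other annotated genes, at log2 -1.51 ± 0.10. The MYC list was not called without OFF24 replicate 3 (camera adjusted p = 0.0508) or without OFF48 replicate 3 (0.0593). Its median log2 change was -0.21 with all libraries, -0.098 without the former and -0.13 without the latter.

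The remaining lists were not called between the times. ATF4 targets had 5 of 24 up and 2 down (5 and 4 when adjusted over the list alone, camera adjusted p = 0.803), with Atf5 at log2 1.13 ± 0.18 (SE) and Ddit4 at -2.07 ± 0.24, and aminoacyl-tRNA synthetases 2 of 20 down (2 when adjusted over the list alone, camera adjusted p = 0.537). One-carbon enzymes had 1 of 15 up, Mthfd2 (log2 0.62 ± 0.11), and 1 down, Mthfd1l (-1.17 ± 0.11), with the same counts when adjusted over the list alone (camera adjusted p = 0.969). Their median was 0.13 and the set test leaned down. ERK output genes had 3 of 13 up and 6 down (the same when adjusted over the list alone, camera adjusted p = 0.25), with Egr1 at log2 1.56 ± 0.26. Etv4 had 8 counts over the OFF24 libraries, with 0 in replicate 1, and 0 over the OFF48 libraries. These are too few to set a bound on its fall between the times. Camera adjusted p-values of the others ran from 0.0519 for lysosomal genes (7 of 29 up and 3 down, 12 and 3 when adjusted over the list alone) to 0.969 for the MLL-AF9 program (3 of 17 up and 1 down, 3 and 2 when adjusted over the list alone, median 0.01 and mean -0.09). G2 and M phase genes had 6 of 30 down (7 when adjusted over the list alone, camera adjusted p = 0.0626), and passed without OFF24 replicate 3 (camera adjusted p = 0.045), OFF48 replicate 1 (0.0246) or OFF48 replicate 2 (0.0389), with upper quartile scaling (0.0465), limma-voom (0.0202), the deposited normalised values (0.0138) and no filter on low counts (0.0119). The lysosomal list passed without any of 5 libraries in turn, for example without OFF48 replicate 1 (camera adjusted p = 0.0243), with RLE (0.0475) or library-size scaling (0.0446), DESeq2 (0.0105), limma-voom (0.0404) and no filter on low counts (0.0103).

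Between OFF24 and OFF48, 1020 genes rose and 1140 fell (2160 together, edgeR quasi-likelihood, BH), 170 and 408 of them at least 2-fold. Under upper quartile scaling the split was 862 up and 1301 down, or 39.9% up against 47.2%. The largest rises, beside Ltf, were those of Rgs5 (log2 3.46 ± 0.19, SE), Cxcl2, a neutrophil chemokine (3.38 ± 0.31), and Chil3 (3.10 ± 0.14). The largest falls were those of Ak4, a mitochondrial adenylate kinase (log2 -5.85 ± 0.30), ND6 (-4.93 ± 0.19), S100a4 (-4.23 ± 0.27, with a shared 3' end) and Itgb7, an integrin subunit (-3.99 ± 0.31). Of the genes called at both times against ON, 62 rose at 24 h and fell at 48 h, and 9 did the reverse.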

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

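The tests that weigh explanations in this part were chosen only after the results were seen, although the other scalings and leaving out OFF48 replicate 2 were settings fixed before, and the counts over other splits of the libraries were set before. The changes at 24 h and 48 h after doxycycline withdrawal, both against ON, differed for 2160 genes by the direct test of OFF48 against OFF24. The same test marked 12 lists whose change differed between the times, 7 of them also with an estimated correlation. By median log2 change from 24 h to 48 h, these were serine synthesis (-0.96), STAT5 targets (-0.99), MYC and ribosome biogenesis (-0.21), glycolysis (-1.29), cholesterol and fatty acid synthesis (-0.41), S phase (0.29), neutrophil maturation (1.36), heat shock (-0.26), mitochondrially encoded genes (-0.47), nuclear OXPHOS subunits (-0.20), mitochondrial proteostasis (-0.36) and ribosomal proteins (-0.42). Those not called with an estimated correlation were serine synthesis, MYC, heat shock, mitochondrially encoded and nuclear OXPHOS.

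Of the named genes, 14 were called in opposite directions against ON at the 2 times, out of 71 such genes among all tested. Their log2 changes from 24 h to 48 h were -1.05 for Adss, -5.85 for Ak4, -2.93 for Aldoc, -1.47 for Ccr2, -0.90 for Cd34, -1.89 for Eno1, -3.99 for Itgb7, -1.17 for Mthfd1l, -4.93 for ND6, -2.88 for Pdk1, -2.31 for Pgk1, -0.67 for Rpl10a and -4.23 for S100a4. Cd63, a tetraspanin of late endosomes, was the only named gene that fell and then rose, with 0.90. Ak4, Cd63, Eno1, Rpl10a and S100a4 share 3' ends with other annotated genes.

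Of 23 glycolysis genes 12 rose at 24 h against ON, a list call lost with an estimated correlation (adjusted p = 0.209) and without ON replicate 3 (camera adjusted p = 0.0512), and the list fell by 48 h. Reads shared with pseudogene copies are argued against as the cause of the fall from 24 h to 48 h. The 16 members whose 3' ends match no other gene had a median log2 change of -1.17 over that time, with 11 of them down. The rise at 24 h was not tested in this way, so shared reads stay open for it. At 24 h the MYC list had fallen (median -1.386) while the glycolysis list had not (median 0.332). The glycolysis value is part of the pattern itself and was known when this comparison was chosen. It is therefore no separate test of lower MYC output as the only cause, which was not decided. A change of oxygen supply between the cultures stays open, because oxygen would follow the groups and was not recorded. Hypoxia-induced genes outside glycolysis, a list of 28 written after the pattern was seen, moved with it (median -1.072 from 24 h to 48 h). Oxygen, nutrient use, the removal of doxycycline itself and the loss of FLT3-ITD thus cannot be told apart here, and the pattern may reflect any of them.

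Serine synthesis genes and ATF4 targets fell after doxycycline withdrawal. Shared 3' ends are argued against for the 24 members without a match, whose median log2 change at 24 h was -1.226, with 21 of them down. The other 3 members, Phgdh among them, are not covered by this. The highest median of the serine list over 5 scalings was -1.427, so the fall did not rest on the scaling chosen among these. The median of all tested genes, 0.031, is held near 0 by scaling and decides nothing. None of these scalings can show a change in total RNA per cell, which stays open. An effect of doxycycline itself could contribute, as the drug inhibits mitochondrial translation, mitochondrial stress can induce ATF4, and withdrawal removes the drug together with FLT3-ITD. Mitochondrial proteostasis genes fell at 24 h (median -0.561), and with no cells that had doxycycline without the FLT3-ITD vector, the drug and the transgene cannot be told apart for these genes. Loss of FLT3-ITD signalling is the biological hypothesis that the design names, and it stays open beside the drug.

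Neutrophil maturation genes rose at 48 h. With S100a8 and S100a9 left out, the other 20 members had a median log2 change of 1.897 against ON, but a larger share of these genes can only lower the others, so this test could not have come out otherwise and decides nothing. Without OFF48 replicate 2, the shallowest library, the list's median was 1.761, which argues against that library alone. A change in cell state after loss of FLT3-ITD stays open and untested, as do an effect of removing doxycycline itself and a change in the mix of cells in the culture.

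For each comparison, the libraries of its groups can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In OFF24 against ON the real split gave 3603 genes, 891 at least 2-fold, in OFF48 against ON 4841 and 1702, and in OFF48 against OFF24 2160 and 578. The highest count of any other split was 0 in each case, so 1 of 10 splits, the real one, gave as many genes. Every other split mixes the groups, which puts the difference between them into the spread. Low counts were to be expected there, so the contrast with the real split decides nothing.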

How the results depend on the processing

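Collapsing rows with the same counts and leaving out S100a8 and S100a9 were chosen after seeing the data. Under all settings run, the 147 alternative counts of changed genes, 2-fold changes and overlap stayed within 1.5 times the reported ones, and no count, list or named gene reversed. The fewest genes were called by DESeq2 against ON (2728 at 24 h, 4135 at 48 h). Of list results, 24 calls were lost, 15 of them with an estimated correlation, 69 were gained, 18 of them with fry, which is another kind of test, and 1908 kept their side of the threshold. Of results for named genes, 143 calls were lost, 35 were gained and 7747 results, called or not, kept their side of the threshold. With an estimated correlation, the serine synthesis list from OFF24 to OFF48 (median log2 -0.957) was no longer called (adjusted p = 0.0573), and the cause was not tested.

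Leaving out each library in turn gave 2846 to 3900 genes for OFF24 against ON (845 to 976 at least 2-fold), 4180 to 4835 for OFF48 against ON (1631 to 1850) and 1506 to 2410 for OFF48 against OFF24 (515 to 591), with 2211 to 2888 shared between both times. The serine synthesis median ran from -1.505 to -1.453, from -2.475 to -2.351 and from -0.991 to -0.868. With the replicate number as a block, 4200, 5189 and 2701 genes were called, and 3 lists were called in addition, the BCL2 family and ER chaperones (adjusted p = 0.0296) for OFF24 against ON and lysosome for OFF48 against OFF24 (adjusted p = 0.0272). The labels do not say what the numbers mark. For that reason they were not taken as pairs in the main fit. The deviations of libraries with the same number correlated at -0.015 to 0.406, over 0.1 in 5 of 9 cases, among them all 3 of replicate 2. In both other groups at once, 3 of 9 libraries correlated best with their own number. A link between libraries of the same number is therefore not excluded, above all between those numbered 2. By the floor of 3 counts, depth limits what a count of 0 excludes to levels above 0.74 CPM in ON replicate 2 and above 2.26 CPM in OFF48 replicate 2.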

Other observations

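The genes in this part were chosen after their values were seen, and so was the list of hypoxia-induced genes. Some receptors and secreted factors of myeloid cells on no list rose after doxycycline withdrawal and others fell, and no test was made of such genes as a class. Cd33, a sialic acid receptor of myeloid cells, had 385 CPM in ON, 888 in OFF24 and 1260 in OFF48, and Clec12a, an inhibitory lectin receptor, 96.9, 214 and 339 CPM. Cxcr4, which holds blood progenitors in marrow, had 126, 314 and 348 CPM, and Il6ra, an interleukin receptor chain, 5.37, 15.7 and 42.5. The complement gene C3 had 211, 449 and 865 CPM, Cybb, the catalytic subunit of the phagocyte oxidase, 7.99, 15.4 and 66.5, and Tnfsf13, a cytokine of the TNF family whose 3' end is shared with another annotated gene, 3.23, 15.5 and 31.0. All 3 tested Ms4a6 genes rose at both times (edgeR, BH), and so did each gene named so far. Other genes fell at both times. Ccl6, a chemokine, had 77.5, 24.1 and 6.97 CPM, and the inhibitory receptor Lilrb4a, whose 3' end is shared with Lilr4b, 46.4, 7.25 and 3.80. Mif, a secreted cytokine whose 3' end is shared with pseudogenes, had 1221, 876 and 116 CPM, Fabp5, a fatty acid carrier, 129, 29.0 and 5.75, and the interferon-inducible Ifitm3 107, 43.8 and 13.5.

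Of 9 tested genes of the S100 family, 6 rose and 3 fell at 48 h against ON (edgeR, BH). S100a6 had 409 CPM in ON, 210 in OFF24 and 15.1 in OFF48, and S100a10 52.5, 44.8 and 5.12, while S100a8 had 9671, 9973 and 32588 and S100a1 63.0, 90.4 and 151. Of 10 genes with a Clec symbol, 5 rose and 3 fell at 48 h. Clec4a2, whose 3' end is shared with Clec4b1, had 27.9, 66.4 and 261 CPM, and Clec4d 17.5, 22.6 and 2.38. Of 5 stefin A genes, 4 were called at 48 h against ON and 4 at 24 h, all as falls, but not the same 4. Stfa1, with 3940, 1763 and 4307 CPM, fell at 24 h and was not called at 48 h (log2 0.13, edgeR adjusted p = 0.285). Csta1, with 3.82, 2.14 and 1.41 CPM, was called only at 48 h. From 24 h to 48 h, 2 of the 5 rose and 0 fell. Stfa3 had 388, 105 and 96.7 CPM. Stfa1 and Stfa2 share 3' ends with relatives and are uncertain.

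Of 28 hypoxia-induced genes outside glycolysis, 15 rose and 6 fell at 24 h against ON (median log2 0.53), 5 rose and 16 fell at 48 h (median -0.76), and 1 rose and 21 fell from 24 h to 48 h (median -1.07). Without adjustment, camera gave 6.14e-04, 1.37e-07 and 3.31e-33, and 0.152, 0.0769 and 0.00213 with an estimated correlation. As the list was written after the pattern was seen in these data, these p-values describe it and are no independent evidence. Egln3, an oxygen-sensing hydroxylase, had 57.1, 139 and 10.5 CPM, and Ankrd37 12.1, 26.7 and 2.02.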
